A study of Mus musculus with 15 samples.

How the data were processed

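Expression was measured by RNA-seq in the tibialis anterior of C57BL/6 mice that had received AAV6 in the hindlimb, with samples taken 2 months after injection. The libraries were made with a stranded mRNA kit, per the labels' protocols. The same protocols speak of hearts where the sample labels name skeletal muscle, so genes of both tissues are reported as a check. The 4 groups were male mock (4 libraries), male C-del (4), female mock (3) and female C-del (4), taken from the sample labels. What C-del stands for is not explained there. Males and females came in 2 separate tables, so sex and table cannot be told apart.

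The values deposited are expected counts per gene, that is, estimated counts that need not be whole: 14.6% to 17.3% of values per library were not whole within 0.001. The design fixed at the start had assumed whole counts, so values were rounded before testing and the planned count test was kept. The deposited counts carry no normalisation. These expected counts, as named here, were made with featureCounts version 2.0.0 on the mouse build GRCm38.p6, per the submitters' processing notes. The aligner, the counting options and the use of strand are not given in the sources used here. Without them, overlapping genes and near-identical copies cannot be separated with certainty, and their values are less sure. Each table had 42396 gene entries, of which 40017 had a symbol found in the RefSeq annotation of GRCm38.p6, and the other 2379 were copies placed at further loci of 1766 genes. 0 entries lacked a gene name. The 13 protein-coding genes of the mitochondrial genome matched no entry and were not analysed here. Female columns carry the numbers of the sample titles. Male columns match the titles by group alone, so male library numbers are column numbers that pair nothing.

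Total counts per library were 14297600 to 15454500 in male mock, 15304500 to 17744000 in male C-del, 9285150 to 10790100 in female mock and 10239300 to 12054900 in female C-del libraries. Pairs of libraries of a group were compared by a chi-square of their counts per gene, which was 2.62 to 43.8, so no library was counted as a copy of another. Tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. Genes were kept by filterByExpr at its default minimum count of 10, scaled with TMM factors and tested with edgeR's robust quasi-likelihood test. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Each sex was fitted alone, while the average effect and the female minus male effect were contrasts in a fit of all 15 libraries. SE is the log2 fold change divided by the root of the F statistic. CPM values use the TMM-scaled library sizes, and scores use log2(CPM + 1), with a pseudocount of 1. Lsmem2 was also compared by an exact two-sided permutation test. Fold changes compare C-del with mock.

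Before the data were examined, the tests, the comparisons, 44 lists of muscle, mitochondrial, stress, immune and cell type genes (1239 names, 1226 matched) and the rule for named genes were fixed. Lists with at least 5 members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. By the rule, Lsmem2 is named in each sex, then the 10 higher and 10 lower passing genes with the smallest adjusted p. These need a mean of at least 1 CPM in the libraries of that sex and a symbol that is not a predicted-gene, clone or receptor segment name, and a tie goes to the larger fold. Up to 4 members of each list follow, passing ones first by smallest p, and for the average and the difference the 5 higher and 5 lower. Genes passing in both sexes in the same direction, up to 10, are named too, and where fewer than 3 genes pass, the 5 with the smallest p are named as not passing. Sex-linked genes and genes of heart and skeletal muscle are named as checks. The rule gave 270 genes. The text names a part of them, picked after their values were seen.

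The gene and list tests were tested on simulated data with the real means and library sizes and 200 changed genes. For males (14543 genes) edgeR made 179 calls, 9 of them false, and recovered 68.8% of 1.5-fold, 90% of 2-fold, 95.7% of 4-fold and 97.9% of 8-fold changes. For females (14220 genes) it made 135 calls, 9 false, and recovered 12%, 55.1%, 96% and 95.7%. For the average (15272 genes) it made 182 calls, 9 false, and recovered 68%, 82%, 98% and 98%. For the difference (15272 genes) it made 135 calls, 9 false, and recovered 18.4%, 58%, 88% and 89.8%. DESeq2 made 182, 162, 190 and 148 calls for males, females, the average and the difference, of which 12, 25, 16 and 16 were false. A list shifted 1.3-fold was called in each of the 4 comparisons, and 0 other lists were. Genes were simulated as independent of one another, whereas members of real lists were correlated (estimated at 0.825 for the cytosolic ribosome in the average). The simulation therefore does not show how often the list test calls real lists by chance. Alternatives fixed at the start were an adjusted p under 0.1, a minimum log2 fold change of 1, RLE size factors, DESeq2, limma voom with sample weights, other filters, a fit that is not robust, Lsmem2 left out, all 15 libraries in the fit, the female title number as a block, and each library left out in turn. Chosen after seeing the data were leaving out male C-del libraries 1 and 2, male mock libraries 3 and 4 or female mock libraries 2 and 3, summing neighbouring male columns, the number of the male columns as a block, adding locus copies to their gene, the overlap and the female splits without Lsmem2, and the list test of the female minus male effect.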

Results

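RNA of the tibialis anterior, a fast muscle of the lower hindlimb, was sequenced from C57BL/6 mice 2 months after the hindlimb had received adeno-associated virus of serotype AAV6. The virus carried either a form of LSMEM2 named C-del or, as the mock control, the green fluorescent protein EGFP. Males gave 4 mock and 4 C-del libraries, and females gave 3 mock and 4 C-del libraries. Total counts per library ran from 14297600 to 17744000 in males and from 9285150 to 12054900 in females. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. In every pair of libraries of a group, counts differed by more than sampling noise, with a smallest chi-square per gene of 2.62.

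The labels name skeletal muscle as the tissue, whereas the extraction text speaks of hearts, so tissue and sex markers were read first. The skeletal muscle genes Acta1, Ckm and Myh4 (skeletal actin, muscle creatine kinase and a fast myosin heavy chain) had means of 28801 ± 1381, 16693 ± 491 and 43844 ± 2187 CPM (counts scaled to library size, SD, n = 4) in male mock libraries. Myh6, the main myosin heavy chain of the adult mouse heart, had a mean of 4.44 ± 1.12 CPM there and of 5.46 ± 1.71 CPM in female C-del libraries (SD, n = 4 each). The heart genes Nppa and Myl7 had group means of at most 0.123 CPM. The Y-linked gene Uty had a mean of 14.5 ± 1.23 CPM in male mock libraries (SD, n = 4) and of 0.132 ± 0.116 CPM in female mock libraries (SD, n = 3). Xist, transcribed from the inactive X chromosome, had a mean of 64.7 ± 2.73 CPM in female C-del libraries and of 0.0142 ± 0.0283 CPM in male C-del libraries (SD, n = 4 each).

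Lsmem2, the delivered gene, lies on chromosome 9 from 107592626 to 107597990 in GRCm38.p6. Its mean was 1497 ± 806 CPM in male C-del and 29.2 ± 0.552 CPM in male mock libraries (SD, n = 4 each). In females it was 1967 ± 582 CPM with C-del (SD, n = 4) and 31.2 ± 1.42 CPM with mock (SD, n = 3). Every C-del library lay above every mock library, and the lowest was male C-del library 1 at 481 CPM. The log2 fold change was 5.68 ± 0.57 (SE) in males (edgeR, adjusted p = 0.00223) and 5.98 ± 0.27 (SE) in females (edgeR, adjusted p = 3.05e-05). An exact two-sided permutation test of log2 CPM gave p = 0.0286 in males and p = 0.0571 in females, each the smallest value its design allows. Without male mock libraries 3 and 4, which left 2, the log2 fold change was 5.66 (adjusted p = 0.0586). Without female mock libraries 2 and 3 it was 6.00, in a run with a single mock library, assumed to vary like the C-del libraries, so that its adjusted p of 0.226 says nothing about stability. Counts at this locus hold both the mouse gene and whatever part of the delivered sequence matches it.

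**Figure D1:**
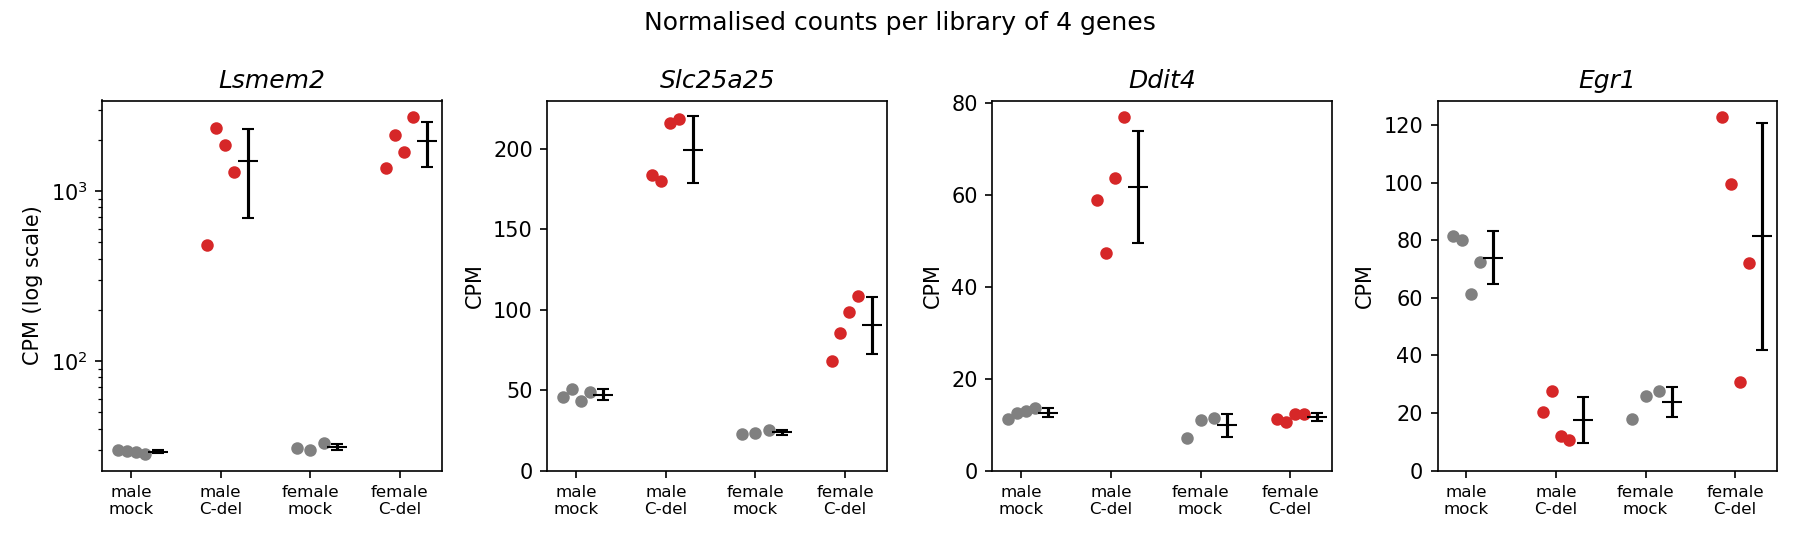
Normalised counts (CPM) of Lsmem2 on a log axis, and of Slc25a25, Ddit4 and Egr1 on linear axes, for each library, with grey points for mock, red points for C-del and bars for mean ± SD (n = 4, 4, 3 and 4). Lsmem2 and Slc25a25 are higher in every C-del library than in every mock library of the same sex, the Ddit4 groups of males do not overlap, and Egr1 is lower with C-del in males (fold 0.24).

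The first comparison asked which transcripts differed between C-del and mock muscle in males. Slc25a25, a mitochondrial carrier of ATP-Mg and phosphate (chromosome 2, 32414487 to 32451470), rose 4.24-fold, from 47.1 ± 3.34 to 199.7 ± 20.7 CPM (SD, n = 4 each; log2 fold change 2.08 ± 0.075, SE; edgeR, adjusted p = 5.77e-09). The stress-induced gene Ddit4, a repressor of mTORC1 signalling, rose 4.91-fold, from 12.6 ± 1.02 to 61.7 ± 12.3 CPM (log2 fold change 2.30 ± 0.15; adjusted p = 3.03e-05). The transcription factors Klf4 and Klf2 rose 2.45-fold and 2.42-fold, the orphan nuclear receptor Nr4a1 rose 1.84-fold, and the endothelin receptor Ednrb rose 2.09-fold. Among genes that fell, Gprc5c was 2.12-fold lower, at 58.7 ± 1.25 against 124 ± 10.2 CPM (log2 fold change -1.08 ± 0.057; adjusted p = 7.99e-08). Socs2, an inhibitor of growth hormone signalling, was 2.69-fold lower and the sodium-calcium exchanger Slc8a3 was 1.52-fold lower. Tmem140 (chromosome 6, 34863146 to 34874946) and Cyren (34871771 to 34878065) fell 1.68-fold and 1.66-fold; they overlap, and with strand use in counting not given, their reads cannot be separated with certainty. In all, 1624 of 14543 genes passed (843 higher and 781 lower), of which 62 were at least 2-fold higher and 48 at least 2-fold lower. With neighbouring columns of each group summed, which left 2 values a group, 272 genes passed, and without mock libraries 3 and 4, which had the highest tendon scores, 767 did. A joint fit of all 15 libraries passed 380 for the male contrast.

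Heat shock and oxidative stress genes formed the list with the smallest p in males. Of 28 members, 15 rose and 0 fell (23 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.56. The chaperones Hsp90aa1 and Hsph1 rose 1.99-fold and 1.63-fold, the constitutive chaperone Hspa8 1.5-fold and the small heat shock protein gene Hspb6 1.71-fold. The list passed camera with a preset correlation (adjusted p = 4.18e-18) and not with an estimated one (adjusted p = 0.0942 with an estimated correlation). Of 23 genes of the glucocorticoid and fasting response, 15 rose and 0 fell (15 higher and 0 lower adjusted over the list alone). Among them were Tsc22d3, a glucocorticoid-induced gene (1.56-fold), Cebpd (2.31-fold), Per1 (1.61-fold) and Ddit4. It was the single list of 41 tested in males that held with an estimated correlation (adjusted p = 4.12e-13 preset, 0.0106 with an estimated correlation). Of 27 immediate early genes 9 rose, Jun by 1.5-fold, and 5 fell (10 higher and 5 lower adjusted over the list alone; adjusted p = 0.000938, and 0.497 with an estimated correlation). Egr1 was among those that fell (log2 fold change -2.06 ± 0.31; adjusted p = 0.0103). Without mock libraries 3 and 4 its adjusted p was 0.0665, and with neighbouring columns summed it was 0.265. The circadian clock list did not pass in males or females (adjusted p = 0.446 and 0.244, and 0.723 and 0.864 with an estimated correlation). Of its 19 members tested in males, Per1, Usp2, Nfil3 and Arntl rose and Rora fell (4 higher and 3 lower adjusted over the list alone; median log2 fold change 0.0023). A score of 11 of its genes, the mean log2 level of Arntl and Clock less that of the others, was chosen after the values were seen and was 0.254 higher with C-del in males (exact two-sided permutation test, p = 0.0286, n = 4 each). Per1, Usp2, Nfil3 and Rora were not among the 11.

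Of 36 complex I genes 4 rose in males, among them Ndufs4 (1.18-fold), and 0 fell (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.00635, and 0.497 with an estimated correlation). Of 78 mitochondrial ribosome genes 8 rose, among them Mrpl4 (1.21-fold), and 0 fell (8 higher and 0 lower adjusted over the list alone; adjusted p = 4.18e-05, and 0.497 with an estimated correlation). Of 30 genes of fatty acid uptake and oxidation 5 rose (8 higher and 1 lower adjusted over the list alone; adjusted p = 2.61e-05, and 0.555 with an estimated correlation). These included the uncoupling protein gene Ucp3 (1.43-fold) and Acsl1, a long-chain acyl-CoA synthetase (1.35-fold). Ppargc1b, a coactivator of mitochondrial genes, rose 1.5-fold, whereas Idh2, the mitochondrial isocitrate dehydrogenase, fell 1.53-fold. The lists of complex IV, complex V and inner membrane import did not pass (adjusted p = 0.304, 0.0819 and 0.245). In the fit of all 15 libraries Ndufs4, Mrpl4, Acsl1, Ucp3 and Idh2 lost their calls (adjusted p = 0.212, 0.204, 0.214, 0.455 and 0.0539), as did the first 3 of them with neighbouring columns summed (adjusted p = 0.113, 0.101 and 0.102) and Mrpl4 without mock libraries 3 and 4 (adjusted p = 0.0589). Their log2 fold changes in the fit of all 15 libraries were 0.24, 0.28, 0.44, 0.52 and -0.61, against 0.24, 0.27, 0.43, 0.51 and -0.61 in males alone.

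Of 38 neuromuscular junction genes 1 rose and 3 fell in males, and the list did not pass (adjusted p = 0.505; 1 higher and 3 lower adjusted over the list alone). Musk, the receptor kinase of the postsynaptic membrane, rose 1.58-fold, from 22 ± 2.2 to 34.8 ± 2.97 CPM (SD, n = 4 each; adjusted p = 0.000133). Gfpt1, the first enzyme of the hexosamine pathway, fell 1.24-fold and Lsmem1 fell 1.48-fold. With neighbouring columns summed, their adjusted p was 0.0861 and 0.111, and Gfpt1 lost its call in the fit of all 15 libraries too (adjusted p = 0.143) and Lsmem1 without mock libraries 3 and 4 (adjusted p = 0.0667). Of 19 pericyte and smooth muscle markers 10 fell, among them Kcnj8 (1.33-fold) and Pdgfrb (1.21-fold), and 1 rose (1 higher and 12 lower adjusted over the list alone; adjusted p = 0.000568, and 0.466 with an estimated correlation). The calls of Kcnj8 and Pdgfrb were lost with neighbouring columns summed (adjusted p = 0.0789 and 0.101), and that of Pdgfrb also in the fit of all 15 libraries and without mock libraries 3 and 4 (adjusted p = 0.166 and 0.0623). Of 15 tendon markers 2 fell, Egr1 and Tnmd, a tenocyte gene whose adjusted p was 0.0438 and whose call held in 10 of 23 alternatives (0 higher and 8 lower adjusted over the list alone; median log2 fold change -1.06; adjusted p = 1.41e-05, and 0.497 with an estimated correlation). The tendon score, a mean log2(CPM + 1), was 4.9 and 4.40 in mock libraries 3 and 4 against 3.92 and 3.86 in mock libraries 1 and 2. Of 26 macrophage markers 0 passed with edgeR (5 higher and 0 lower at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone), 1 was higher with DESeq2, and the list passed camera as higher (adjusted p = 0.00212, and 0.703 with an estimated correlation). Its score was 3.21 and 3.38 in C-del libraries 1 and 2 and 2.00 and 2.20 in C-del libraries 3 and 4. Without C-del libraries 1 and 2 the macrophage list pointed the other way (adjusted p = 0.0811). In all, 15 of the 41 lists passed, 13 higher and 2 lower, of which 1 held with an estimated correlation, and fry passed 13; the number was 9 without mock library 2, and other splits of the 8 libraries passed up to 25.

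The same question was asked in females. Lsmem2 and Slc25a25 were the 2 genes of 14220 that passed, both higher. Slc25a25 rose 3.79-fold, from 23.8 ± 1.49 CPM in mock (SD, n = 3) to 90.3 ± 17.6 CPM with C-del (SD, n = 4; log2 fold change 1.92 ± 0.17, SE; edgeR, adjusted p = 0.00485). Without mock library 3, which left 2, the log2 fold change was 1.97 and the gene no longer passed (adjusted p = 0.0665). The next genes did not pass, each with an adjusted p of 0.0686. Their log2 fold changes were 2.88 ± 0.37 (SE) for Apold1, 1.65 ± 0.21 for the kinase gene Sik1, 1.26 ± 0.17 for Bcl6b, 1.15 ± 0.14 for Klf10 and 1.08 ± 0.15 for Nr4a1. An unadjusted p under 0.05 was reached by 1692 genes, where chance gives 711 on average. Genes are not independent of one another, so the number by chance can lie far from that. Other splits of the libraries were not counted for it. DESeq2 called 376 genes (118 higher and 258 lower), the joint fit of all 15 libraries called 777, and without mock library 1 edgeR called 1050 (114 higher and 936 lower).

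Immune genes set female mock libraries apart from one another. The antigen presentation score was 5.78 and 5.43 in mock libraries 2 and 3, 3.25 in mock library 1 and 2.93 to 3.31 in the C-del libraries. The macrophage score was 4.60 and 3.74 in mock libraries 2 and 3 and 2.15 in mock library 1. With edgeR over all genes, 0 of 25 antigen presentation genes, 0 of 41 interferon response genes and 0 of 26 macrophage markers passed. At an unadjusted p under 0.05, 25, 33 and 22 were lower with C-del, and DESeq2 called 24, 21 and 10 lower. Adjusted over the list alone, 25, 31 and 22 were lower and 0 higher. Iigp1, an interferon-induced GTPase gene, had a mean of 328 ± 272 CPM in mock and 12.1 ± 1.01 CPM with C-del (SD, n = 3 and 4; adjusted p = 0.12). Ptprc, the pan-leukocyte marker CD45, had 33.5 ± 40.9 and 1.71 ± 1.09 CPM (adjusted p = 0.156), with 2.96, 79.9 and 17.7 CPM in mock libraries 1, 2 and 3. The score of B and plasma cell markers, of which 5 were tested, was 7.55 in mock library 2, 2.43 in mock library 3 and 2.53 in mock library 1. Against mock library 1 alone, the log2 fold changes of Iigp1 and Ptprc went from -4.77 and -4.30 to -0.82 and -0.78. Camera with a preset correlation passed 17 of 42 lists in females, 11 higher and 6 lower. Immediate early genes were among the higher ones (median log2 fold change 0.71; 0 of 27 passed with edgeR, 14 higher at an unadjusted p under 0.05, 10 higher with DESeq2, 13 higher and 0 lower adjusted over the list alone; adjusted p = 5.69e-11), with Fos at 9.57 ± 4.69 CPM in mock and 47.5 ± 15.5 CPM with C-del. None of the 17 held with an estimated correlation (adjusted p = 0.532 to 0.769 with an estimated correlation), fry passed 0, and other splits of the 7 libraries passed up to 22.

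**Figure D2:**
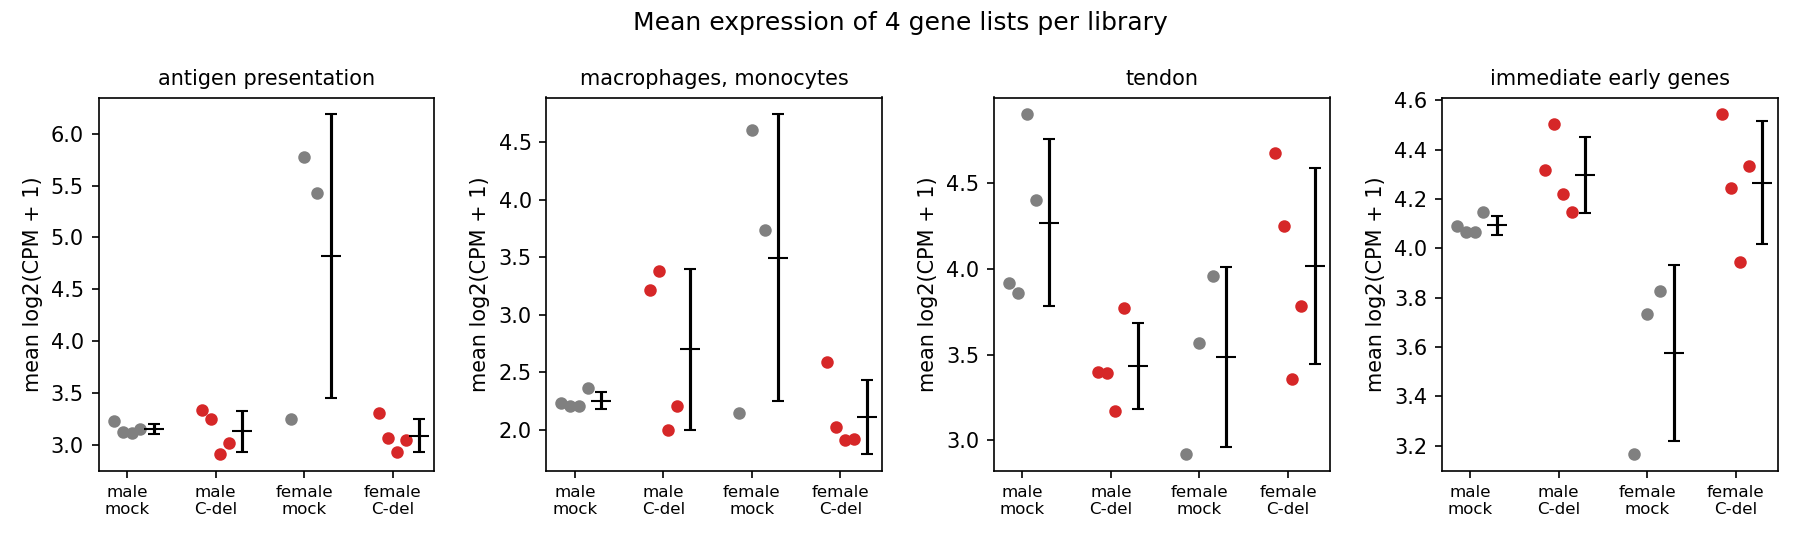
Mean log2(CPM + 1) of the genes of 4 lists in each library, with grey points for mock, red points for C-del and bars for mean ± SD (n = 4, 4, 3 and 4). Female mock libraries 2 and 3 lie above the other female libraries for antigen presentation (5.78 and 5.43) and macrophage markers (4.60 and 3.74), and male C-del libraries 1 and 2 lie above the other male libraries for macrophage markers (3.21 and 3.38).

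The effects of both sexes were then averaged in a fit of all 15 libraries. Slc25a25 rose 4.01-fold (log2 fold change 2.01 ± 0.094, SE; edgeR, adjusted p = 2.61e-09), Ednrb 2.08-fold, Nr4a1 1.97-fold, Klf4 2-fold and Tob2, an antiproliferative gene, 1.74-fold. Lratd2 fell 1.62-fold and Fbp2, the muscle fructose bisphosphatase, fell 1.55-fold. Of 28 heat shock and oxidative stress genes 10 rose (15 higher and 1 lower adjusted over the list alone; adjusted p = 1.5e-11, and 0.11 with an estimated correlation), with Dnajb1 up 2.23-fold. In females alone 0 of the 28 passed with edgeR (4 higher and 2 lower at an unadjusted p under 0.05, 1 higher and 2 lower with DESeq2, 3 higher and 2 lower adjusted over the list alone), and the list did not pass (median log2 fold change 0.033; adjusted p = 0.169). Of 24 glucocorticoid and fasting genes 9 rose (12 higher and 0 lower adjusted over the list alone; adjusted p = 3.72e-11, and 0.00797 with an estimated correlation), and in females alone the list had a median log2 fold change of 0.19 (adjusted p = 0.00751, and 0.532 with an estimated correlation). Of 27 immediate early genes 13 rose and 0 fell (14 higher and 2 lower adjusted over the list alone; adjusted p = 7.44e-11, and 0.284 with an estimated correlation). Of 25 antigen presentation and 42 interferon genes 13 and 13 fell and 0 rose (adjusted p = 1.5e-11 and 3.72e-11, and 0.575 and 0.598 with an estimated correlation; 0 higher and 24 lower, and 0 higher and 24 lower, adjusted over the list alone). In these lists female mock libraries 2 and 3 stood apart, and in males alone neither list passed (median log2 fold change -0.035 and -0.012; adjusted p = 0.446 and 0.657). The list with the smallest p in the average was the cytosolic ribosome. Of its 86 genes 0 rose and 1 fell, with a median log2 fold change of -0.17 (0 higher and 1 lower adjusted over the list alone; adjusted p = 4.64e-13, and 0.623 with an estimated correlation). In females alone 0 of the 86 passed, with a median of -0.33 (adjusted p = 6.1e-18, and 0.726 with an estimated correlation). In all 673 of 15272 genes passed, 369 higher and 304 lower. Without female mock libraries 2 and 3, which left 1 female mock library, the number was 669, of which 341 were shared with the 673 genes. Without any 1 of the male mock libraries, male C-del libraries 1, 2 or 3, or female C-del libraries 2, 3 or 4 it was 368 to 443, and without female mock library 1 it was 2085. It was 192 without male C-del libraries 1 and 2, and 218 without male mock libraries 3 and 4. Musk (log2 fold change 0.49 ± 0.099; adjusted p = 0.00972) lost its call without each of these pairs of libraries (adjusted p = 0.0517, 0.0699 and 0.0631) and with voom and sample weights (adjusted p = 0.0798). Of 42 lists 18 passed, 13 higher and 5 lower, of which 1 held with an estimated correlation, 6 passed with fry and 10 passed without female mock libraries 2 and 3, and other splits passed up to 28.

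Whether the effect differed between the sexes was tested as the female minus the male log2 fold change. Ddit4 rose in males and stood at 9.8 ± 2.41 and 11.6 ± 0.903 CPM in female mock and C-del libraries (difference -2.06 ± 0.23, SE; edgeR, adjusted p = 0.00058). Gprc5c fell in males and had 40.8 ± 2.35 and 39.2 ± 2.71 CPM in females (difference 1.02 ± 0.11; adjusted p = 0.00058). Socs2 and Mcf2l, a guanine nucleotide exchange factor gene, differed by 1.94 ± 0.26 and 1.31 ± 0.16. Hsp90aa1 and the cochaperone gene Dnaja1 differed by -0.95 ± 0.14 and -0.82 ± 0.12. Egr1 differed by 3.82 ± 0.58 (adjusted p = 0.0225), with 23.8 ± 5.25 CPM in female mock and 81.3 ± 39.6 CPM in female C-del libraries. Lsmem2 itself differed by 0.30 ± 0.55 (adjusted p = 0.81). In all 54 of 15272 genes passed, 26 with a higher and 28 with a lower effect in females. The number was 5 with limma voom and sample weights, 656 with DESeq2, and 9 and 6 without male C-del libraries 1 and 2 or male mock libraries 3 and 4. It was 1817 without female mock library 1, 141 without female mock library 2, and 10 to 35 without any 1 of the male libraries, female mock library 3 or female C-del libraries 2, 3 or 4. Of the 18 genes named for this contrast, 1, Gprc5c, kept its call in every alternative run other than a minimum fold. Sex and sequencing table coincide, so a difference between sexes cannot be told apart from one between the tables.

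Calls of both sexes were compared over the 14022 genes tested in both with edgeR, or 14012 with DESeq2. Higher calls shared 2 genes, where independent lists of these sizes give 0.118 (one-sided Fisher exact test, p = 0.00345). One of them is the delivered gene, shared by design. Without Lsmem2 the shared gene was Slc25a25, against 0.0587 (one-sided Fisher exact test, p = 0.0587). At an unadjusted p under 0.05, 231 genes were higher in both sexes against 88.5 for independent lists (one-sided Fisher exact test, p = 1.14e-47), and 114 were lower in both against 124 (p = 0.862, one-sided Fisher exact test). DESeq2 calls shared 56 higher genes against 6.68 (p = 1.5e-38) and 22 lower genes against 11.1 (p = 0.0018, one-sided Fisher exact test for each). Genes are not independent of one another, so these p-values describe the lists. Of 1594 genes called in males, Lsmem2 left out, 59.5% had the same sign in females, and 9 of the 35 splits of the female libraries gave as large a share (exact one-sided permutation p = 0.257). Across all genes, which are not independent replicates, the log2 fold changes of the sexes had a Pearson correlation of -0.0066 and a Spearman correlation of 0.036. Over the 1594 genes called in males, with female effects taken as differences of mean log2(CPM + 1), as for the share of signs, the Pearson correlation was 0.297, and 5 of the 35 splits of the female libraries gave one as large.

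**Figure D3:**
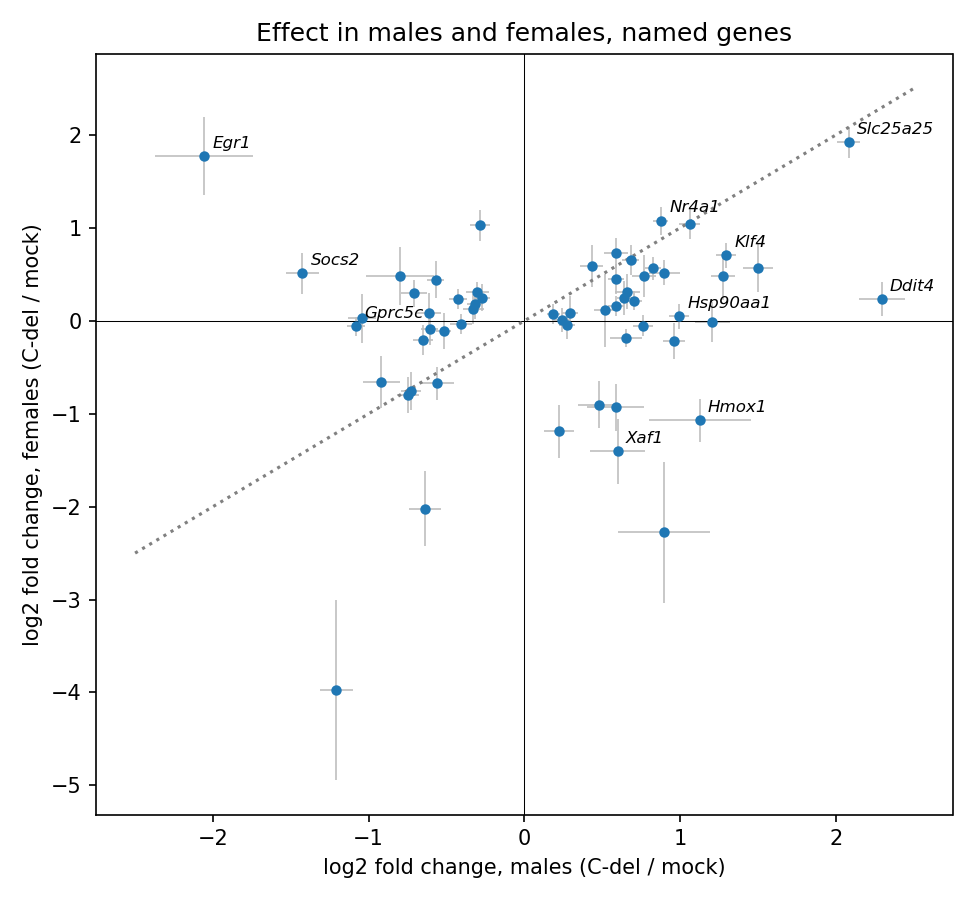
Log2 fold change (C-del over mock) in males (x axis) and females (y axis) of 58 genes named for the male comparison or the difference between sexes, without Lsmem2, with bars for SE and a dotted line where both are equal. Slc25a25 lies near the line (2.08 in males, 1.92 in females), whereas Egr1 has opposite signs (-2.06 and 1.77) and Ddit4 lies far below the line (2.30 and 0.24).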

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

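The tests of immune cells, of a construct effect common to both sexes, of the time of day and of handling, and the list test of the female minus male effect, were chosen after the results were seen.

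In 294 groups of 4 values, 19 had a library whose gap to its nearest neighbour took an unusually large share of the group's range, where chance gives 14.7. In male mock libraries these shares were 0.854 for Ucp3 in library 1, 0.839 for Myh6 in library 2, 1 for Myl7 in library 2 (the other libraries at 0), 0.929 for the list of genes higher after denervation in library 1, 0.837 for the macrophage list in library 4 and 0.960 for the interferon list in library 1. In male C-del libraries they were 0.971 for Klf2 in library 4, 0.864 for Cyren in library 3, 0.847 for Per1 in library 3, 0.879 for Pdgfrb in library 2, 0.900 for Xaf1 in library 3 and 1 for Xist in library 2 (the others at 0). In female C-del libraries they were 0.850 for Cd68 in library 1, 0.842 for Tob2 in library 4, 0.830 for Mcf2l in library 3, 0.872 for Hmox1 in library 1, 0.892 for the proliferation list in library 1, 0.884 for the interferon list in library 3 and 0.851 for the cytosolic ribosome list in library 1.

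The effect of C-del differed between the sexes for 54 genes (edgeR, adjusted p under 0.05). The female minus male log2 fold change was 1.02 for Gprc5c, 1.31 for Mcf2l, 1.94 for Socs2, 0.999 for the Notch ligand gene Jag1, 0.66 for Hs2st1, 3.82 for Egr1 and 0.61 for Mylk. It was -2.06 for Ddit4, -0.95 for Hsp90aa1, -0.82 for Dnaja1, -1.18 for Tmem37, -0.84 for Smox, -2.20 for Hmox1, -1.23 for Cebpd, -2.01 for Xaf1, -1.53 for Ifit1, -1.39 for Aldh18a1 and -1.42 for Ly6c2. Except for Gprc5c, each of these lost its call in at least 1 alternative other than a minimum fold. Without female mock libraries 2 and 3, whose immune genes were high, 1 female mock library was left. There the difference was -0.93 for Xaf1, -1.06 for Ifit1, -0.94 for Aldh18a1 and -0.58 for Ly6c2, nearer to none. That of Egr1 (4.24) and Smox (-0.87) did not shrink. Sex and table cannot be told apart in any of these differences.

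Of 42 lists 18 passed camera for the female minus male effect, and 0 of the 18 held with an estimated correlation (adjusted p = 0.126 to 0.854 with an estimated correlation). Median differences (log2) above 0 were 0.0715 for the TCA cycle, 0.242 for the dystrophin complex and costamere, 0.152 for endothelial markers, 0.371 for pericyte and smooth muscle markers, 1.45 for tendon markers and 0.628 for immediate early genes. Those below 0 were -0.171 for complex I, -0.102 for glycolysis, -0.224 for the integrated stress response, -0.169 for the unfolded protein response, -0.434 for heat shock, -1.12 for proliferation, -1.49 for interferon, -2.29 for antigen presentation, -3.12 for macrophages, -0.144 for the mitochondrial ribosome, -0.314 for the cytosolic ribosome and -0.206 for glucocorticoid and fasting genes. With 1 library left out, the camera adjusted p reached 0.842 for the TCA cycle, 0.48 for immediate early genes and 0.391 for the unfolded protein response. It reached 0.381 for glycolysis, 0.233 for the mitochondrial ribosome and 0.0955 for complex I. For glucocorticoid and fasting genes, endothelial markers and proliferation it reached 0.0825, 0.0711 and 0.0522. The other lists stayed under 0.05. Each of these runs keeps at least 1 of female mock libraries 2 and 3, whose immune genes were high. They thus cannot show whether the lists rest on that pair. Without both, which left 1 female mock library, the cytosolic ribosome list turned in direction.

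Immune genes stood out in female mock libraries 2 and 3. A construct effect common to both sexes is argued against, since the antigen presentation list had a median log2 fold change of -0.0355 in males (SD over members 0.333) and of -2.47 in females (SD 0.869). The members moved together (estimated correlation 0.938 in females), so these SDs do not measure the spread between libraries. Sex or table alone is argued against, since female mock library 1 (antigen presentation score 3.25) and the female C-del libraries (2.93 to 3.31) share both and lack the pattern. Immune cells in that tissue may be the source and stay open, because the libraries were picked for their immune genes, so that the 21 of 26 macrophage markers higher in both than in every other female library restate the pattern. The 2 libraries were not alike, with Ptprc at 79.9 and 17.7 CPM (2.96 in mock library 1) and a B and plasma cell score of 7.55 and 2.43 (2.53 in mock library 1).

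The median log2 fold change of immediate early genes was 0.34 in males and 0.71 in females. The same handling difference in both sexes stays open. The effect of Egr1 differed between sexes (edgeR, adjusted p = 0.0225), but Egr1 was picked after this had been seen, so it cannot decide the question. Its difference lost its call in 7 of 28 alternatives. Its fall in males had an adjusted p of 0.265 with neighbouring columns summed (edgeR). Time of day of dissection may contribute in males, where a clock score of 11 genes was 0.254 log2 units higher with C-del and the groups did not overlap (exact two-sided permutation test, p = 0.0286, the smallest 4 against 4 allows). In females the score differed by 0.216 with overlapping groups (p = 0.514, exact two-sided permutation test), which leaves it open. The score and its criterion were chosen after the values were seen, in 2 forms. The other form gave 0.230 and 0.178 (exact two-sided permutation p = 0.0286 and 0.571). Neither form holds Per1 or Usp2, members of the clock list that rose in males. Counted among the subtracted genes, they would lower the difference in males. The evidence is therefore weak, and an effect of the construct remains open. The clock list fixed before the data were examined did not pass in males or females (camera, adjusted p = 0.446 and 0.244). Camera tests a shift of a whole list in a single direction, whereas the score sets Arntl and Clock against the other genes. The list result thus cannot decide on the time of day.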

How the results depend on the processing

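The runs without pairs of libraries, with summed columns, with locus copies added and with the male column number as a block, the overlap without Lsmem2, and every list result of the female minus male effect, were chosen after the results were seen. Lsmem2 and a minimum fold aside, 29 of 46 passing genes rerun for males, 21 of 23 for the average, 1 of 18 for the difference and 0 of 1 for females kept their call in every alternative, and of the 47, 24, 23 and 18 genes rerun for males, females, the average and the difference, all but Mki67 in females kept their direction. The simulated test found 12% of 1.5-fold changes in females. Depth was lower there, and the mock group had 3 libraries. These also differed more from one another, with a chi-square per gene of 25.2 to 43.8 between pairs, against 2.62 to 9.49 in male mock. Causes were not tested except where fewer samples or another threshold give one by construction.

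The 1624 genes of males were 2446 at an adjusted p under 0.1, 110 with a log2 fold change of at least 1, 380 with all 15 libraries in the fit, 767 without mock libraries 3 and 4, 272 (261 shared) with columns summed, and 1100 to 1526 with 1 library left out. The Lsmem2 log2 fold change was 5.66 without mock libraries 3 and 4 (5.37 to 5.98 with 1 library left out), where its adjusted p no longer passed. The 2 genes of females were 16 at an adjusted p under 0.1, 376 with DESeq2, 16 without a filter, 1 without Lsmem2, 777 with all 15 libraries in the fit (262 higher and 515 lower), 6 with locus copies added, 4 without mock libraries 2 and 3 (0 shared) and 1 to 1050 with 1 library left out (1050 without mock library 1, 1 without mock library 3). Without female mock libraries 2 and 3 a single female mock library remained, assumed to vary like the other libraries fitted, so a call lost or a list turned there in females says nothing about stability. The female Lsmem2 log2 fold change was 6.00 there (5.78 to 6.12 with 1 library left out) without passing, and that of Mki67 turned to 2.15.

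The 673 genes of the average were 1248 at an adjusted p under 0.1, 138 with a log2 fold change of at least 1, 1096 with DESeq2, 383 with voom and sample weights, 192 without male C-del libraries 1 and 2, 218 without male mock libraries 3 and 4 and 368 to 2085 with 1 library left out. The 54 genes of the difference were, in the same order, 614, 28, 656, 5, 9, 6 and 10 to 1817. Genes shared by the sexes were 14 at an adjusted p under 0.1, 78 with DESeq2, 345 at an unadjusted p under 0.05 and 1 without Lsmem2. RLE factors moved no split of higher and lower genes by more than 10 points.

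With an estimated correlation the lists passing were 1 in males, 0 in females, 1 for the average and 0 for the difference, and with fry 13 in males, 0 in females, 6 for the average and 4 for the difference. Without female mock libraries 2 and 3 10 lists passed for the average. With 1 library left out, the lists were 9 to 18 in males (9 without mock library 2), 15 to 23 in females, 13 to 23 for the average and 16 to 22 for the difference. The direction turned for macrophage markers in males without C-del libraries 1 and 2 (adjusted p = 0.0811). Without female mock libraries 2 and 3, with 1 female mock library left, it turned in females for fusion and fission (adjusted p = 0.622), fatty acid uptake and oxidation (0.456), proliferation (0.976) and the cytosolic ribosome (0.450). There it also turned in the average for proliferation (0.779) and macrophages (0.243), and in the difference for the TCA cycle (0.575), the unfolded protein response (0.755), proliferation (0.903) and the cytosolic ribosome (0.155). In the difference, complex I and the mitochondrial ribosome turned without female mock library 3 (adjusted p = 0.0266 and 0.233), with ranges of 5.44e-12 to 0.0955 and 5.44e-12 to 0.233 with 1 library left out.

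Female title numbers did not pair the libraries: same-numbered libraries had correlations of deviations of -0.13, -0.008 and -0.041. With the number as a replicate block 2 genes and 17 lists passed. Male titles share no number between the groups. The numbers of the male columns did not pair them either, with correlations of -0.0126, -0.0491, -0.106 and 0.021. With the column number as a replicate block 1162 genes (1110 shared with the 1624) and 12 lists passed in males.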

Other observations

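The tests of neighbouring columns, the female splits without Lsmem2 and the list test of the female minus male effect, whose splits are counted too, were chosen after the results were seen, and the other counts of splits were planned.

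In the average over both sexes, 5 of 21 slow fibre genes rose and 0 fell (8 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.00915, and 0.598 with an estimated correlation). With 1 library left out, the adjusted p of the slow fibre list reached 0.0763. The LIM protein gene Fhl1 of this list rose 2.22-fold. Myh2, the myosin heavy chain of type 2A fibres, belongs to the list of sarcomere and fast fibre genes. It rose 1.72-fold (log2 fold change 0.78 ± 0.11, SE; edgeR, adjusted p = 0.000759). Of the 26 sarcomere and fast fibre genes 3 rose and 1 fell, and the list did not pass (4 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.971). Of 27 genes of the dystrophin complex and costamere 5 rose and 0 fell (5 higher and 0 lower adjusted over the list alone; adjusted p = 1.28e-05, and 0.295 with an estimated correlation), among them Flnc, filamin C (1.64-fold), whose call was lost without female mock libraries 2 and 3, male C-del libraries 1 and 2 or male mock libraries 3 and 4 (edgeR, adjusted p = 0.141, 0.0768 and 0.0876). Of 24 endothelial markers 3 rose and 1 fell (8 higher and 1 lower adjusted over the list alone; adjusted p = 4.85e-05, and 0.165 with an estimated correlation). The water channel gene Aqp1 rose 1.31-fold and the transcription factor Sox18 fell 1.68-fold. In females alone these slow fibre, costamere and endothelial lists passed (adjusted p = 0.0134, 1.82e-05 and 7.49e-05; 0.726, 0.532 and 0.532 with an estimated correlation) and in males alone they did not (adjusted p = 0.0787, 0.142 and 0.178). With 1 library left out, the adjusted p of the slow fibre list in females reached 0.152. For the female minus male effect the slow fibre list did not pass (camera, adjusted p = 0.448). There the costamere and endothelial lists passed (adjusted p = 0.00557 and 0.00765), though not with an estimated correlation (0.64 and 0.489).

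Neighbouring male columns resembled each other. In each group, deviations from the group mean had correlations of 0.0206 to 0.147 within columns 1 and 2 and within columns 3 and 4 (4 pairs) and of -0.600 to -0.459 between them, across genes that are not independent. By chi-square per gene, C-del libraries gave the same pairs, with 4.83 and 4.56 within them and 12.1 to 14.7 between. Among mock libraries, 3 and 4 were the closest (2.62), but library 1 was nearer to library 4 (4.59) than to library 2 (6.03). Library size is argued against as the whole cause, since the nearest totals gave the same pairing in 1 of the 2 groups. A shared source of each pair, such as an animal or a preparation, may account for it. If each group held pairs in a random order of columns, the pairs would be neighbours in both groups in 11.1% of cases. That share takes no account of how far the correlations within and between pairs lie apart. No biological explanation was tested.

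Other splits of the libraries were counted with every column as a unit. In males 1 of 35 splits, the real one, gave as many genes as the 1624, and the highest other gave 2. Chance is excluded there only if the columns are independent: with neighbouring columns as 1 unit there are 3 splits, too few for a share under 0.05. The same limit holds for the male part of the average, where 1 of 100 splits gave as many as the 673, the highest other giving 25. In females 1 of 35 gave as many as the 2, and the highest other gave 0. Lsmem2 is high in every C-del library by design, and without it 1 of 35 gave as many as the 1 gene left, Slc25a25, the highest other giving 0. Chance is excluded for that gene only if the female libraries are independent, which the labels do not say, and these splits were counted after its call had been seen. The call was lost without mock library 3. For the difference 2 of 100 gave as many as the 54, and the other of them gave 120 with the male groups as they are and female libraries exchanged. The male effect stays in the contrast of that split, so its number does not show what chance alone gives. Whether the male effect accounts for the 120 was not tested. That split calls more than the real one, so little rests on the share. Chance is not excluded for the number of lists: as many came from 7 of 35 splits in males (real 15, highest other 25), 20 of 35 in females (17 and 22), 36 of 100 for the average (18 and 28) and 25 of 100 for the difference (18 and 25).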
